A study of Sus scrofa with 6 samples.

How the data were processed

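Gene expression was measured in alveolar macrophages of 6 pigs, 3 infected with SS2 and 3 given PBS, on 1 Affymetrix porcine array per pig. Per the labels' protocols, lungs were lavaged with 100 mL aliquots of PBS with gentamicin at 70 µg/mL, the fluid was spun at 230 g for 15 min, cells were washed in medium with gentamicin at 50 µg/mL, total RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 µg of it. No sorting step is described, so other lavaged cells can be present. Groups were taken from the titles, source names and treatment labels, which call the samples biological replicates; the disease state label reads healthy for all 6 samples, infected ones included, so it does not tell whether the infected pigs were ill.

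The deposited values are MAS5 signals, the intensity of a probe set on a linear scale, per the submitters' processing notes and the values. The version of MAS5, its scaling target, detection calls and any genome build are not given in the sources used here. The trimmed mean signal was 230.5 to 235.6 in 5 arrays and 380.1 in control 3, so that array was not on the common level. MAS5 subtracts background and averages the probes of a set robustly, so low signals are noisy, and 16 was added before log2 to damp them. A fold change on this scale understates the change of dim genes. A probe set also reads only the sequence it was designed on, so a gene with many alleles, such as the swine leukocyte antigens, can read differently between pigs.

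The deposited table held 24123 probe sets without missing values. The 124 array control probe sets (AFFX) were left out, and of the remaining 23999 the lowest 30% by mean log2 signal over all 6 arrays, which left 16800. Gene symbols came from the platform annotation supplied with the data. Of the deposited probe sets 10140 had 1 symbol, 157 several and 13826 none; among those tested the counts were 8255, 128 and 8417. Genes were named only from probe sets with 1 symbol, which gave 5889 genes. For gene lists the probe set of highest mean signal stood for its gene. No coordinates are given, since no build is named for the files.

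Infected and control arrays were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes with an intensity trend, two-sided, with group as the only term, and Benjamini-Hochberg adjustment at 0.05. Gene lists were tested with camera at a preset correlation of 0.01 between genes, two-sided, with adjustment over the 36 lists, which were fixed with 979 gene symbols before the data were examined and each had at least 5 measured genes. Camera with an estimated correlation and fry were run beside it. A list score is the mean of the median-centred log2 values of its genes in an array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined, except where an alternative is said to have been added.

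Genes were named by this rule: probe sets with 1 symbol past adjusted p under 0.05, an absolute log2 change of at least 1 and no overlap between groups, up to 12 each way, filled to 12 by the smallest unadjusted p among those with the same size and no overlap; up to 4 members of each list with the smallest p; and 12 immune genes. Since none passed, all of the first kind were filled, and only 8 higher ones met the size and overlap terms. The rule covered 157 probe sets of 156 genes; the text gives the leading ones and summarises the rest as counts.

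The steps were tested on simulated data with the means of the 16800 probe sets and their spreads as moderated by eBayes, 200 of them changed. Moderation draws the spreads towards the intensity trend, so they were more alike than in the data. Of 100 changed by 2 (log2) 92% were called and of 100 changed by 1, 18%, with 10 false calls. After median centring these were 93%, 44% and 17. A list of 20 genes shifted by 0.5 was called in the right direction, with 0 of the other 35 lists called, for independent genes. The simulated noise was drawn independently for each probe set and array, without a shift of any whole array.

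Alternatives were pseudocounts of 1 and 64, median centring, quantile normalization, no filter on dim probe sets or the lowest 50% left out, no intensity trend, robust eBayes, array weights, the replicate number as a block, each array left out in turn, and for lists an estimated correlation, fry and the mean over a gene's probe sets. Added after seeing the data were median centring without control 3, without control 1, with the block, and with the mean log2 3' to 5' ratio of 3 control genes as a covariate. The labels give no scan date or batch. With 3 arrays against 3, an exact permutation test of a single value cannot give a p below 0.1, so none is used to call a difference.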

Results

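Alveolar macrophages, the resident phagocytes of the air spaces of the lung, were collected by lavage from 6 Large White pigs. The 3 infected pigs had received Streptococcus suis serotype 2 (SS2) strain SC19 through the nose, a bacterium that causes meningitis, septicaemia and pneumonia in pigs. The labels give an inoculum volume of 2 mL and a dose of 4840000 colony-forming units. The 3 control pigs had received the same volume of phosphate-buffered saline (PBS). The pigs were 28 days old at inoculation and the cells were taken 7 days later. RNA of each pig was hybridised to 1 Affymetrix porcine array, which reads each transcript through a probe set, so a group holds 3 biological replicates. The comparison asks which transcripts of the lavaged cells differ between infected and mock-inoculated pigs 7 days after inoculation. Levels below are MAS5 signals as mean ± SD over the 3 arrays of a group, and changes are log2(signal + 16) differences, infected minus control, with their standard error.

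The 6 arrays were not all on one level. The array of control 3 had a median signal of 102.68, against 65.43 to 67.68 in the other 5, or 1.55 times their mean. Its mean correlation with the other arrays across probe sets was 0.931, against 0.955 to 0.968. The signal at the 3' end of a transcript relative to its 5' end, which rises as RNA or cRNA becomes shorter, was lowest there. By this measure control 3 was not the array with the shorter RNA. The GAPDH ratio was 2.72 in control 3 and 3.29 in control 1, and 7.00 to 9.22 in the other 4 arrays. In actin and EF1A control 1 was not low, at 8.32 and 2.55, against 7.70 to 15.2 and 1.70 to 2.57 in these 4. Control 3 read 3.38 and 1.20. Control 1 differed in other control probe sets. Its BioB spike-in signal was 767 (286 to 422 in the others), that of 18S ribosomal RNA 1883 (647 to 879) and that of 28S 5677 (2514 to 3046). It lay at -39.8 on the second principal component, with the others between -1.17 and 18.7. Median centring, which brings the arrays to 1 level, raised each change by 0.23 (log2), and the centred value is given beside each deposited one. The number of arrays, 3 in each group, limits the precision of all values.

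**Figure D1:**
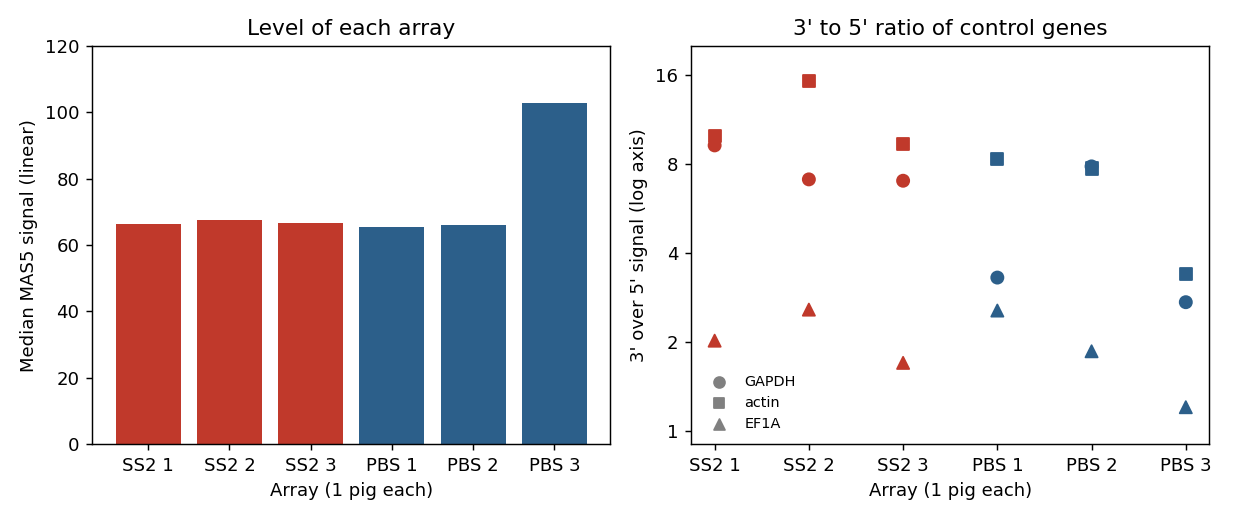
Left, the median MAS5 signal of each array on a linear axis from 0, 1 bar per pig. Right, the ratio of 3' to 5' signal of GAPDH, actin and EF1A control probe sets on a log axis, with SS2-infected pigs in red and PBS controls in blue; control 3 has the highest median, 102.68, and the lowest ratio of all 3 genes.

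No sorting step is described for the lavaged cells, so a signal need not come from macrophages. TCN1, which encodes a vitamin B12-binding protein, had a signal of 907 ± 521 in infected pigs against 178 ± 59.7 in controls. Its change was 2.15 ± 0.41 (2.38 ± 0.36 centred). EPHX2, the soluble epoxide hydrolase, read 279 ± 37.2 against 106 ± 40.6 (1.33 ± 0.32, centred 1.56 ± 0.28). CCL2, the chemokine that draws monocytes, read 275 ± 227 against 74.4 ± 28.1 (1.46 ± 0.51, centred 1.69 ± 0.54). On the lower side, the MHC class II chain SLA-DRB1 read 3711 ± 285 against 7185 ± 2267 (-0.91 ± 0.23, centred -0.68 ± 0.11), and TREM1, a receptor that amplifies inflammatory signalling, 117 ± 31.8 against 399 ± 274 (-1.46 ± 0.46, centred -1.22 ± 0.34). TCN1, EPHX2, CCL2 and TREM1 were picked among probe sets whose groups did not overlap, so that trait adds no support. The groups also did not overlap for SLA-DRB1, but it was named for a small p within its list, which favours such gaps. No gene passed the test after adjustment.

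Among 16800 probe sets tested with limma, 0 passed Benjamini-Hochberg adjustment at 0.05, and the smallest adjusted p was 0.845. At an unadjusted p under 0.05 there were 253 probe sets, 60 higher and 193 lower in infected pigs, where chance alone gives 840. The groups did not overlap in 9.02% of probe sets as deposited, 130 higher and 1386 lower, where chance gives 10%. After median centring it was 7.68%, with 795 higher and 495 lower. At 2-fold and an unadjusted p under 0.05 there were 67 probe sets, 24 higher and 43 lower. That count was 119 without infected 1, 151 without infected 2, 370 without control 1 and 282 without control 2. The direction depended on the scaling and on single arrays. The share of higher probe sets among those at unadjusted p under 0.05 was 23.7% as deposited and 68.7% after median centring (327 higher, 149 lower), which also called 0 probe sets. As deposited it was 65.5% without control 3, 49.7% without infected 1, 11.5% without control 1 and 8.99% without control 2. Simulated changes put into data with the spreads moderated by eBayes were recovered in 92% of cases at a log2 change of 2 and in 18% at a log2 change of 1. These spreads were more alike between probe sets than in the data. The simulated noise was independent between probe sets and held no array on another level, as control 3 was. These shares may therefore overstate recovery in the real arrays.

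The genes that led the comparison by the rule fixed beforehand numbered 8 higher and 12 lower. None of the 20 passed adjustment. Probe sets without a gene symbol could not be named, and some had a smaller p or larger gap than these genes, with changes of 1.96, -2.42 and -3.78. Of 157 named probe sets, 127 moved by over 1.5 times or changed sign as deposited when 1 array was left out, 91 of them without control 3. Besides TCN1, EPHX2 and CCL2, the higher ones were FABP4, a fatty acid-binding protein of mature macrophages (1.72 ± 0.51, centred 1.95 ± 0.54), CD55, a brake on complement (1.30 ± 0.33, centred 1.53 ± 0.44), the pyrimidine-degrading enzyme DPYS (2.91 ± 0.91, centred 3.14 ± 1.04), SULT1A3 and DNAJA4. A second CD55 probe set with a higher signal gave 0.49 (centred 0.72). The DPYS signal was 1109 and 471.74 in infected pigs 2 and 3 but 32.78 in infected 1, close to the controls at 18.16 to 31.08. Without infected 1, DPYS passed with a change of 4.22 and an adjusted p of 0.00394. The lower ones, with TREM1, were the metallothionein MT3 (-1.72 ± 0.47, centred -1.49 ± 0.63), the transporter SLCO3A1 (-1.34 ± 0.34, centred -1.11 ± 0.23), DNASE1L1, ABHD4, APOE, SEMA4D, CHD4, LOC100524254, BZW1, ADIPOR2 and TUBB4B. Without control 3, TREM1 gave -0.95, LOC100524254 -0.51, CHD4 -0.45, ADIPOR2 -0.43, TUBB4B -0.41 and BZW1 -0.37, and without control 1 APOE gave -0.63. Centred, MT3 gave -0.85 without control 1 and -2.20 without control 3. Without infected 3, CCL2 gave 0.85, SULT1A3 0.59, DNAJA4 0.39 and SEMA4D -0.72, and without infected 2 FABP4 gave 1.02. Other probe sets of some of these genes moved less. The brightest SLCO3A1 probe set gave -0.26 (centred -0.03), that of BZW1 -0.33 (centred -0.10) and that of CHD4 -0.41 (centred -0.18). A second DNAJA4 probe set gave -0.04 (centred 0.20), a second DPYS probe set 0.22 (centred 0.45) and dimmer ones of ABHD4 and ADIPOR2 -0.12 and -0.43 (centred 0.11 and -0.20). The APOE probe set named here was dim, at 107 ± 8.5 against 274 ± 170, and the brightest APOE probe set gave only -0.26 ± 0.15 (centred -0.03 ± 0.21).

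**Figure D2:**
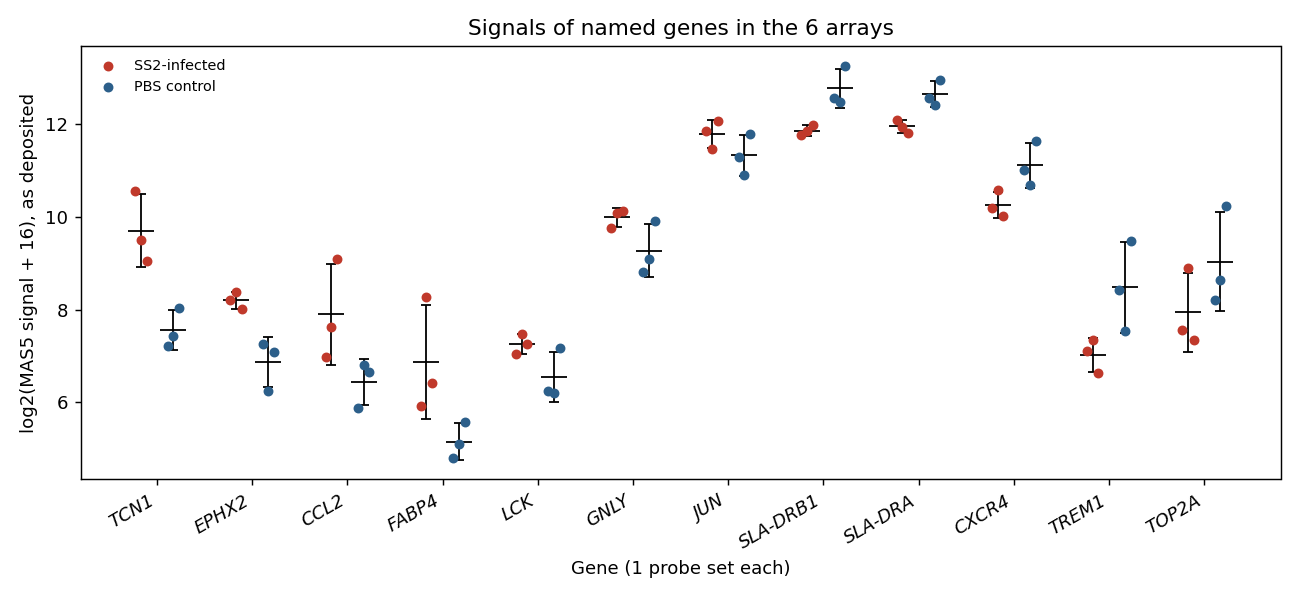
Each point is log2(MAS5 signal + 16) of 1 pig, as deposited, for 12 named genes, red for SS2-infected and blue for PBS control; the horizontal mark is the group mean and the bar its SD over 3 arrays. SLA-DRB1, SLA-DRA, CXCR4 and TREM1 have all infected points below all control points, and TCN1, EPHX2, CCL2 and FABP4 all above, as deposited. TCN1, EPHX2, CCL2, FABP4 and TREM1 were picked among probe sets without overlap. SLA-DRB1, SLA-DRA and CXCR4 were named among the members of their lists with the smallest p, which favours such gaps.

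Of 36 gene lists fixed beforehand, 15 stood apart from the other genes by camera with a preset correlation of 0.01 between genes, 12 ranked higher and 3 ranked lower in infected pigs. With an estimated correlation, 0 lists were called, and the adjusted p of these 15 lists lay between 0.698 and 0.798. The fry test of each list alone also called 0. Camera sets the mean test statistic of a list against that of the other genes. The median change over all tested probe sets was -0.19 as deposited. In 6 of the 12 lists ranked higher the median of the list itself was below 0 while the test pointed up: alveolar macrophage markers, stroma and endothelium, apoptosis, lysosome, alternative activation and complement. The mean change, in that order, was 0.14, 0.06, 0.01, -0.04, -0.14 and 0.04, so in some of these lists it lay above 0 although the median did not. In no list did a member pass adjustment over all probe sets, and 0 members passed when adjusted over the list alone as deposited. After centring 6 genes passed when adjusted over the list alone, SLA-DRB1 (MHC class II), GNLY (NK), LCK and CD8A (T cell), CCL3L1 (chemokines) and DDIT4 (glycolysis and hypoxia), with adjusted p from 0.00577 to 0.0174.

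The MHC class II and costimulation list, which holds the molecules that present antigen to helper T cells, ranked lower (adjusted p = 6.0e-05 by camera; adjusted p = 0.798 with an estimated correlation). All 15 measured members had a lower mean in infected pigs as deposited, and 10 of 15 after centring, with a median of -0.46 (centred -0.23). The classical chain SLA-DRA read 3962 ± 384 against 6452 ± 1308 (-0.69 ± 0.20, centred -0.46 ± 0.13). SLA-DMA and SLA-DMB, which load peptides, gave -0.60 ± 0.23 and -0.65 ± 0.25 (centred -0.37 ± 0.15 and -0.42 ± 0.14). A second bright SLA-DMA probe set gave 0.02 (centred 0.26), the other direction, and a dim SLA-DRB1 probe set -0.30 (centred -0.07). In the leading probe sets of these 3 genes, as in SLA-DRB1, the groups did not overlap as deposited. The centred list score of control 1 was the highest of the 6 arrays, at 10.9, and the other 2 controls read 10.5, beside infected values of 10.3 to 10.5. Centred and without control 1 the median was -0.10 (adjusted p = 0.00743). The cytokine receptor list also ranked lower (adjusted p = 0.0403; 0.798 as adjusted p with an estimated correlation), with a median of -0.37 (centred -0.14). That call ended without infected 1, 2 or 3 and without control 2 or 3, with adjusted p from 0.0510 to 0.262. Its leading member was the chemokine receptor CXCR4, at 1227 ± 249 against 2280 ± 788 (-0.85 ± 0.30, centred -0.62 ± 0.17).

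Markers of cytotoxic lymphocytes ranked higher. The natural killer (NK) and cytotoxic list had 5 of 7 measured members higher, 6 of 7 after centring, and a median of 0.26 (centred 0.49; adjusted p = 0.000108 by camera, adjusted p = 0.698 with an estimated correlation). GNLY, a pore-forming protein of killer cells, read 1006 ± 137 against 637 ± 273 (0.72 ± 0.32, centred 0.95 ± 0.17). The cytokine gene IFNG gave 0.66 ± 0.29 (centred 0.89 ± 0.45; 0.32 centred without control 3) and PRF1 -0.25 ± 0.21 (centred -0.02 ± 0.14). The T cell list had 8 of 12 members higher, 9 after centring, with a median of 0.07 (centred 0.30; adjusted p = 0.0131 by camera, adjusted p = 0.798 with an estimated correlation). LCK, the kinase of the T cell receptor, read 139 ± 22.6 against 81.9 ± 39.4 (0.72 ± 0.31, centred 0.95 ± 0.16), and CD8A gave 0.62 ± 0.35 (centred 0.85 ± 0.19). CD8B and IL7R gave negative values, -0.71 ± 0.48 and -0.38 ± 0.17 (centred -0.48 ± 0.36 and -0.15 ± 0.17), but CD8B gave -0.03 centred without control 3, which read 213 where the other controls read 43.8 and 35.2. The T cell call ended without infected 2, control 1 or control 2, and without control 2 its median was -0.09 (adjusted p = 0.280).

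Immediate-early genes, the transcription factors and regulators induced within minutes of a stimulus, ranked higher with the smallest p of all lists (adjusted p = 2.8e-08 by camera; adjusted p = 0.798 with an estimated correlation). Of 20 measured members 15 had a higher mean in infected pigs, and 20 after centring, with a median of 0.24 (centred 0.47). JUN read 3575 ± 732 against 2633 ± 815 (0.46 ± 0.27, centred 0.69 ± 0.19), EGR1 gave 0.74 ± 0.53 (centred 0.97 ± 0.45) and ATF3 0.68 ± 0.48 (centred 0.91 ± 0.48). Without control 1, EGR1 gave 0.16 and ATF3 0.09 (centred 0.51 and 0.44). The heat-shock and unfolded protein list ranked higher as well (adjusted p = 6.0e-05; adjusted p = 0.798 with an estimated correlation), with 15 of 24 members higher, 21 after centring, and a median of 0.07 (centred 0.30). The chaperone HSP90AB1 gave 0.39 ± 0.28 (centred 0.62 ± 0.24) and HSP90AA1 0.27 ± 0.20 (centred 0.50 ± 0.19) in its brightest probe set and -0.36 to 0.19 (centred -0.13 to 0.42) in 4 others, while XBP1 gave -0.31 ± 0.27 (centred -0.08 ± 0.18). Without control 1, HSP90AB1 gave 0.08 and HSP90AA1 0.06 (centred 0.43 and 0.41). The centred immediate-early score was 9.30, 9.58 and 9.84 in controls and 9.99 to 10.1 in infected pigs. Without control 1, which had the lowest score, the immediate-early median was -0.06 as deposited (adjusted p = 0.00868) and 0.29 centred (adjusted p = 0.0470). The heat-shock call ended without infected 3 (median -0.09, adjusted p = 0.422) and without control 1 (median -0.16, adjusted p = 0.115).

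**Figure D3:**
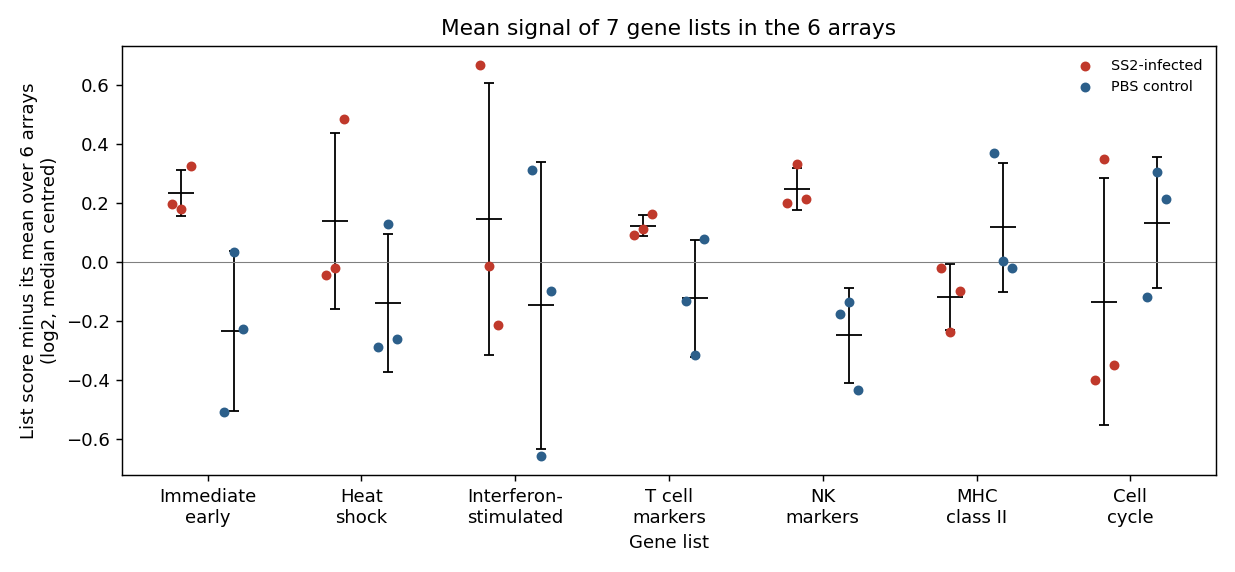
Each point is the mean log2 value of a gene list in 1 pig after median centring, less the mean of that list over the 6 arrays, for 7 lists; red marks SS2-infected pigs, blue PBS controls, the horizontal mark the group mean and the bar its SD over 3 arrays. Infected and control pigs do not overlap for the immediate-early, T cell and NK lists. They overlap for the heat-shock, interferon-stimulated, MHC class II and cell cycle lists. Of all 36 lists, the only other one without overlap is the cytokine receptor list, where chance gives 10% of lists. The T cell gap is narrow, with a list score of 6.67 in infected 1 against 6.65 in control 3.

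Interferon-stimulated genes, which respond to viral and bacterial infection, ranked higher (adjusted p = 0.000455; adjusted p = 0.798 with an estimated correlation) with 15 of 27 members higher, 22 after centring, and a median of 0.06 (centred 0.29). The guanylate-binding protein gene GBP1 read 439 ± 36.4 against 287 ± 206 (0.80 ± 0.44, centred 1.03 ± 0.29), and PML gave -0.40 ± 0.38 (centred -0.17 ± 0.40). GBP1 gave 0.37 without control 2, and PML 0.29 centred without control 1. Cell cycle genes ranked lower (adjusted p = 0.000455; adjusted p = 0.798 with an estimated correlation), with 27 of 27 members lower, 23 after centring, and a median of -0.43 (centred -0.20). TOP2A, the topoisomerase of dividing cells, read 261 ± 176 against 618 ± 497 (-1.09 ± 0.57, centred -0.86 ± 0.47), BIRC5 gave -0.78 ± 0.39 and UBE2C -0.81 ± 0.41 (centred -0.55 ± 0.27 and -0.58 ± 0.37). TOP2A gave -0.50 centred without control 3, and as deposited BIRC5 gave -0.45 without control 3. Both calls ended without infected 1 or without control 2. The interferon list then had medians of -0.27 (adjusted p = 0.877) and -0.35 (adjusted p = 0.840) without these pigs. The cell cycle list kept its direction, with adjusted p of 0.0810 and 0.374.

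Chemokines ranked higher (adjusted p = 0.0198; adjusted p = 0.798 with an estimated correlation) with a median of 0.01 (centred 0.24), but members went both ways and the call ended after centring (adjusted p = 0.419). CCL4 read 741 ± 280 against 393 ± 138 (0.86 ± 0.37, centred 1.09 ± 0.29), CCL3L1 gave 0.67 ± 0.33 (centred 0.90 ± 0.16), and CXCL16 read 1254 ± 182 against 2560 ± 1606 (-0.86 ± 0.39, centred -0.63 ± 0.24, and -0.39 centred without control 3). Markers of alveolar macrophages ranked higher with a median of -0.07 (centred 0.16; adjusted p = 0.0139, adjusted p = 0.798 with an estimated correlation). The call ended with quantile normalization (adjusted p = 0.136), without control 1 (0.115), without control 3 (0.362), centred without control 3 (median 0.01, adjusted p = 0.356) and centred with the 3' to 5' ratio as a covariate (median 0.00, adjusted p = 0.717). The scavenger receptor CD163 read 11431 ± 1681 against 9389 ± 2489 (0.30 ± 0.21, centred 0.53 ± 0.14). The lysosome list had a median of -0.07 (centred 0.16; adjusted p = 0.0400), alternative activation -0.04 (centred 0.19; adjusted p = 0.0403), complement -0.08 (centred 0.15; adjusted p = 0.0403), apoptosis -0.18 (centred 0.05; adjusted p = 0.0264) and stroma and endothelium -0.06 (centred 0.17; adjusted p = 0.0171). With an estimated correlation all 5 had an adjusted p of 0.798. The lysosome call held after centring (adjusted p = 0.00348) but ended centred without control 3 (median 0.06, adjusted p = 0.356) and, as deposited, without infected 1, infected 3, control 1 or control 3 (adjusted p from 0.115 to 0.362). After centring the calls of alternative activation (adjusted p = 0.0720), complement (0.419), apoptosis (0.359) and stroma and endothelium (0.359) ended. In complement, C3 read 6899 ± 1751 against 9505 ± 615 (-0.49 ± 0.21, centred -0.26 ± 0.23) and CLU 94.8 ± 60.3 against 38.2 ± 10.6 (0.92 ± 0.35, centred 1.15 ± 0.35, and 0.50 as deposited without infected 3).

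The other 21 lists were not called, with adjusted p from 0.0632 to 0.990. They held pattern recognition, inflammatory cytokines, NF-kB and its negative regulators, MHC class I and antigen processing, phagocytic receptors, oxidative burst and antioxidants, antimicrobial peptides and iron, coagulation and tissue remodelling, adhesion and migration, lipid uptake and PPARG, cholesterol synthesis, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, and the markers of recruited monocytes, neutrophils, B and plasma cells, epithelium, red cells, mast cells and eosinophils, and dendritic cells. Single arrays and the scaling decided some of these at the preset correlation. Without infected 1 the airway and alveolar epithelium list was called, with a median of 0.34 (adjusted p = 3.5e-07), against -0.15 (adjusted p = 0.0632) with all arrays. Cholesterol synthesis was called without control 1 (adjusted p = 0.00213) and without infected 3 (adjusted p = 0.0284). With all arrays and an estimated correlation the adjusted p of both lists was 0.798. Ribosomal proteins were called after centring (51 of 57 members higher, median 0.14, adjusted p = 2.8e-05) and without control 3 (adjusted p = 0.00141), against a median of -0.09 and an adjusted p of 0.266 as deposited. With quantile normalization their median was 0.02 (adjusted p = 0.816), and with an estimated correlation as deposited the adjusted p was 0.932.

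Of 12 immune genes fixed in advance, 10 were tested and none passed. The inflammatory cytokine gene TNF read 740 ± 269 against 454 ± 259 (0.76 ± 0.42, centred 0.99 ± 0.48), IL1B 101 ± 3.8 against 219 ± 167 (-0.77 ± 0.43, centred -0.54 ± 0.28) and the neutrophil chemokine gene CXCL8 669 ± 786 against 1229 ± 895 (-1.28 ± 0.76, centred -1.05 ± 0.75). The bacterial sensors TLR2 and TLR4 gave -0.37 ± 0.31 and -0.15 ± 0.24 (centred -0.14 ± 0.21 and 0.08 ± 0.16, so that the sign of TLR4 depended on the scaling). CD14, MYD88 and NOS2 gave -0.50 ± 0.35, -0.33 ± 0.26 and -0.23 ± 0.20 (centred -0.27 ± 0.22, -0.10 ± 0.17 and 0.00 ± 0.17). A second, dimmer CD14 probe set gave -0.11 (centred 0.12). Centred without control 3, IL1B gave -0.24, TNF 0.64, TLR2 -0.08, CD14 -0.16, MYD88 -0.21 and NOS2 -0.13. CXCL8 gave -2.22 without infected 2 and -0.68 without infected 3. IL6 and IL10 were on the array but among the dim probe sets left out.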

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

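The count of 0 probe sets past adjustment stayed at 0 with either pseudocount, median centring, quantile normalization, either filter, no trend, robust eBayes and array weights, with smallest adjusted p from 0.304 to 0.996. The settings with median centring and without control 3, without control 1, with the block or with the 3' to 5' ratio were added after seeing the data. They also gave 0. Leaving out single arrays gave 0 to 1: DPYS without infected 1 (4.22, adjusted p = 0.00394) and an unnamed probe set without control 1 (-2.38, adjusted p = 0.0322). The 3 same-numbered infected and control arrays did not deviate together (r = -0.04, -0.09 and -0.06). No label says what the replicate numbers mean, and so few values cannot exclude that they pair pigs. With the replicate block as deposited, 66 probe sets passed (22 higher, 44 lower), 12 of 157 named probe sets among them, 173 stood at 2-fold and unadjusted p, and 9 lists were called; with median centring and the block the first count was 0, so the 66 depended on the scaling.

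At 2-fold and unadjusted p the count of 67 became 39 with a pseudocount of 64, 118 centred with the 3' to 5' ratio, and 65 to 370 without single arrays, 119 without infected 1, 151 without infected 2, 370 without control 1 and 282 without control 2; the cause was not tested. At unadjusted p under 0.05 the share of higher probe sets, 23.7%, became 68.7% with median centring, 56.6% with quantile normalization, 54.1% with array weights, 60.3% and 58.8% centred without control 3 and without control 1, 63.0% centred with the block and 54.9% centred with the 3' to 5' ratio. Without single arrays it ranged from 8.99% (without control 2) to 65.5% (without control 3), with 11.5% without control 1 and 49.7% without infected 1; the cause was not tested.

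The count of 15 lists became 9 with quantile normalization, 8 centred without control 3, 7 centred with the 3' to 5' ratio, 0 with an estimated correlation, 0 with fry, and 7 to 12 without single arrays (9 without infected 1, 7 without control 2, 8 without control 3). Robust eBayes does not enter camera, so it gave no separate list count. Over 20 settings other than the estimated correlation and fry, the MHC class II and immediate-early calls were kept in 20, NK in 19, interferon, heat shock and cell cycle in 18 each, T cell in 16, and the other 8 in 3 to 12. With fry the direction was opposite to that of camera in 18 of 36 lists. Of the 15 called lists 4 were among these, and their medians, which fry does not change, were 0.0106 for chemokines, -0.0815 for complement, -0.0734 for lysosome and -0.175 for apoptosis; fry does not compare a list with other genes. The stroma and endothelium list was not called but pointed lower without control 3 (adjusted p = 0.709), where its median was -0.0395 in a range of -0.0926 to 0.0140 without single arrays. It also pointed lower, uncalled, centred without control 3 (-0.0494, adjusted p = 0.718) and centred with the 3' to 5' ratio (-0.161, adjusted p = 0.380). Oxidative phosphorylation, at -0.16 with all arrays as deposited (adjusted p = 0.992 with an estimated correlation), pointed higher centred with all arrays, uncalled (median 0.07, adjusted p = 0.440), and was called centred without control 1 (0.141, adjusted p = 0.0291). Of 157 named probe sets, 12 changed sign with median centring, 3 with quantile normalization, 20 centred with the 3' to 5' ratio and 27 centred without control 1, and none of these had passed. Dim probe sets limit the reading of weak transcripts such as IL6 and IL10, which fell under the filter.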

Other observations

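Camera at both correlations, median centring, quantile normalization, the other splits for the 2-fold count, and the rule that named DDIT4 and LCK were set beforehand. The rest of the tests and genes in this part, the pan-T set included, were chosen after the results were seen. The measures and bounds of several tests were changed after their first values were seen. After median centring, the genes with the smallest p included the following, none past adjustment over all probe sets (adjusted p = 0.996 by limma). DDIT4, an inhibitor of mTOR signalling induced by stress and glucocorticoids, gave 0.91 ± 0.15 and RGS2, a brake on G protein signalling, 1.08 ± 0.19. The sphingosine-1-phosphate receptor gene S1PR1, which guides lymphocytes out of tissue, gave 1.102 ± 0.24. DGAT2, which makes triglycerides, gave 0.87 ± 0.18, and GGH, which trims folates in the lysosome, 0.62 ± 0.12. Centring moved every change by the same amount, less than any of these 5, so their sign as deposited could not differ. Each of the 5 also kept its sign centred without control 3, but they were picked by p on these same arrays.

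With 6 arrays there are 10 splits into 3 and 3, too few for a share under 0.05. As deposited, the real split gave 0 probe sets past adjustment and the highest other split 1. At 2-fold and unadjusted p the real split gave 67 and the highest other 147. For lists the real split gave 15 and the highest other 10. After median centring these were 0 and 1, 72 and 75, and 11 and 8.

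Markers of T and NK cells ranked higher in infected pigs at the preset correlation, and neither list was called with an estimated one (adjusted p = 0.798 and 0.698). With the 3' to 5' ratio as a covariate the NK score differed by 0.31 ± 0.043 (SE), from 0.50 ± 0.10 before. The T cell score differed by 0.44 ± 0.067, from 0.25 ± 0.12. In that fit the camera call of the NK list ended as its difference shrank (adjusted p = 0.0714). The T cell list was called there at the preset correlation (adjusted p = 3.9e-06). Both scores thus still differed, but the ratio was itself correlated with group (r = 0.68) over only 6 arrays. The fit therefore cannot exclude RNA length for either list. A hypothesis is that lavages of infected pigs may hold more lymphocytes, as no sort would remove them. The 6 pan-T genes CD3D, CD3E, CD3G, CD247, CD2 and LCK were all higher after centring, with a median of 0.35. Their mean was 6.37 to 6.62 in infected pigs and 5.97 to 6.24 in controls, a gap that chance gives in 10% of cases. The changes ran from 0.08 for CD3D to 0.95 for LCK, more unequal than their errors (heterogeneity chi-square 17.5, a criterion added after the equal direction had been seen). That criterion cannot decide, since it takes genes as independent and the scale understates changes of dim genes. More lymphocytes thus stay open as a hypothesis, as does a change within the same lymphocytes or within macrophages after infection. Of the 7 NK genes, 1 is in another list. A lower share of macrophages is also open, since T and NK markers exceeded those of 6 other cell types by 0.18 ± 0.20 (SE between arrays). The macrophage marker score, which a lower share would lower, was 0.37 ± 0.15 higher, with 12 of 15 members higher after centring. That mean included FABP4 at 1.95, while the centred list median was 0.16, and the call of this list ended in several settings. A first form of the marker comparison, against 3 other cell types with genes permuted, gave a difference of 0.33 (permutation p = 0.0072) and would have excluded a lower share. It was replaced because genes are not independent replicates. The high baseline of neutrophil markers was a further reason, but the form used still includes those markers.

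Immediate-early and heat-shock genes ranked higher in infected pigs at the preset correlation, and neither list was called with an estimated one (adjusted p = 0.798 for both). Handling of the cells and RNA length could each contribute, and the mean log2 3' to 5' ratio was 2.26 to 2.70 in infected pigs and 1.15, 2.04 and 2.27 in controls. The immediate-early score differed by 0.47 ± 0.16 (SE) over all arrays, by 0.47 ± 0.21 without control 3, by 0.33 ± 0.11 without control 1 and by 0.45 ± 0.26 with the ratio as a covariate, the last 3 each within the 95% bound of their error, so none of these explanations is excluded. The heat-shock score differed by 0.22 ± 0.27 without control 3, 0.20 ± 0.27 without control 1 and 0.24 ± 0.34 with the ratio, which decides nothing. By camera both lists were still called centred without control 3 (adjusted p = 1.8e-05 and 0.000984) with the ratio (adjusted p = 0.000130 and 0.00142) and centred without control 1 (adjusted p = 0.0470 for both), a test that takes genes as nearly independent. Infection, RNA length and the profile of single control arrays cannot be told apart here, because the arrays are too few, and handling was not tested.

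Control 3 stood apart from the other 5 arrays. Unequal scaling alone does not account for it: after quantile normalization control 3 still lay at the end of the first component, which held 42.2% of the variance, and had the lowest mean correlation with the others, 0.939 against 0.957 to 0.969. RNA or cRNA of different length, longer in control 3 by this measure, is a candidate explanation, since the 3' to 5' ratio was lowest there for all 3 control genes. No biological explanation, such as a difference of that pig, was tested.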
